A study of Marchantia polymorpha with 2 samples.

How the data were processed

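Gene expression was measured by RNA sequencing in the gametophytic thallus of the liverwort Marchantia polymorpha, the flat haploid plant body that dominates its life cycle. The line carried 2 transgenes. One expressed the homeodomain gene MpKNOX2 from the constitutive EF1 promoter. The other held MpBELL1 under the XVE system, in which an estrogen-responsive transcription factor switches the gene on when 17-β-estradiol is supplied. Gemmae, the asexual propagules of the plant, were grown for 10 days at 23°C under 24 h light before their transfer to medium with 5 µM estradiol or to mock medium, and both samples analysed here were frozen 72 h later. The labels give 1 mock and 1 estradiol sample, so each group had 1 library. Samples from 0 h, and plants without the transgenes exposed to estradiol, were not analysed here.

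Per the submitters' processing notes, the reads went through FastQC, STAR and HTSeq. Their versions and settings, the genome build, the use of strand and the normalization method were not given in the sources used here. The identifiers carry the gene model suffix v3.1. The authors deposited 1 table of normalized counts, a non-negative signal per gene, for 16280 genes that each had at least 1 read in at least 1 library. Each deposited value was a whole multiple of the smallest value above 0 in its column, to within 3.63e-05 reads. One read was worth 0.995 normalized counts in the estradiol library and 1.01 in the mock library, which gave the read numbers behind the values. The second deposited table was the authors' own comparison. It repeated both columns with 0 replaced by 0.5 and added, per the file headers, a log2 ratio of estradiol over mock, the absolute difference of the normalized counts, a ranking value, a probability score from 0 to 1, and a tag of up or down. The deposited log2 ratio equalled the log2 of the 2 columns to within 4.86e-07. All 3854 genes with a probability of 0.9 or more were tagged, and none below it. How the probability was made was not given in the sources used here, and it was not treated as a p-value.

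The deposited identifiers were compared with a reference table of 18391 genes, assembly MpTak2_v7.1, and 0 of them matched a locus tag, symbol or synonym. The files do not pair identifiers with gene names. For that reason the levels of MpBELL1 and MpKNOX2, and the 22 gene lists fixed by name (among them cellulose synthases, pectin synthesis and modification, phenylpropanoid enzymes, photosynthesis and sperm markers), were not analysed here. By the rule fixed for genes without names, 2 identifiers that were higher and 2 that were lower are given. With a pseudocount of 10, they had the largest log2 ratios among genes tagged by the authors in that direction with a mean normalized count of 50 or more.

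The ratio of estradiol to mock was computed as log2 of (normalized count + 10), which understates the change of genes with low counts. Genes with a mean normalized count of 10 or more over the 2 libraries entered the counts of genes at least 2-fold higher or lower. With 1 library per group there was no measure of the variation between plants, no p-value across samples was computed, and none of the differences had a replicate check. Counting error was described by exact (Clopper-Pearson) 95% intervals of the ratio, conditional on the reads of both libraries, and by 100 Poisson draws in which the libraries did not differ. Reads without molecular identifiers are not independent molecules, so these intervals and the limit of 3 reads used for a count of 0 cover counting error only. The authors' calls were counted from the deposited tags, because the table held no adjusted p as had been planned.

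The counts and intervals were tested on simulated data drawn from the real gene levels of these 2 libraries over 16280 genes. Changes were planted only in genes with an expected normalized count of 50 or more, so recovery below that level was not tested. All 108 genes changed 4-fold and all 92 changed 8-fold were recovered in the right direction, and 3 of 12650 unchanged genes were counted as 2-fold different. The intervals held the true ratio for 95.8% of genes. Both simulated libraries were Poisson draws, so these figures cover counting error only and not variation between plants. The design, the rule for named genes and most alternatives were set before the data were examined. The alternatives were another pseudocount (1 or 50), no filter or a mean of 100 or more, rescaling to equal totals or to a median log2 ratio of 0, and other fold thresholds. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 was used.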

Results

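The data compared 2 libraries of one inducible line, mock and estradiol, each from thalli sampled 72 h after transfer. KNOX and BELL proteins are partner homeodomain transcription factors of the TALE class, and per the series title the study asked what class II KNOX and BELL genes tell about secondary cell wall and pectin synthesis in land plants. The estradiol library held 13103037 reads in genes and the mock library 15495357. At least 1 read was found for 15703 genes in the estradiol library and for 15040 in the mock library. A gene with no read could have been present at a level of up to 3 reads, or 2.99 normalized counts in estradiol and 3.04 in mock, the limit that a count of 0 allows.

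The estradiol and mock libraries differed widely. Of 12854 genes with a mean normalized count of 10 or more, 1930 were at least 2-fold higher in the estradiol library than in mock (15.0%) and 2337 were at least 2-fold lower (18.2%). A difference of at least 4-fold was found for 667 genes in the higher direction and 821 in the lower, and of at least 8-fold for 233 and 184. Another 6246 genes (48.6%) lay within 1.5-fold. The median log2 ratio was -0.03, a value that the scaling of the libraries largely sets, and 80% of genes lay between -1.61 and 1.37.

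Counting error accounted for few of these differences. In 100 Poisson draws with no difference between the libraries, at most 4 genes came out 2-fold higher and at most 5 genes 2-fold lower. The 95% counting interval of the ratio lay wholly beyond 2-fold for 1538 of the higher and 1917 of the lower genes. These figures compare the 2 libraries and not the 2 conditions, since the variation between plants of one treatment was not measured. The balance between directions depended on the scaling. With both libraries set to the same total, which moved the median log2 ratio of all genes to 0.23, 2527 genes were higher and 1827 lower, so that the higher genes went from 45.2% to 58.0% of the genes that differed.

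The largest log2 ratios with a pseudocount of 10 lay far outside counting error. Mapoly0004s0175.1.v3.1 had 15754 normalized counts in estradiol and 9.11 in mock, a ratio of 1730 with a 95% counting interval of 911 to 3783. Mapoly0051s0074.1.v3.1 had 1177 in estradiol and 3.04 in mock (3 reads), a ratio of 388 with an interval of 132 to 1883. In the other direction, Mapoly0026s0025.1.v3.1 had 29.9 normalized counts in estradiol and 13171 in mock, so that the mock level was 441 times the estradiol level, with an interval of 309 to 654. Mapoly0057s0102.1.v3.1 had 46.8 in estradiol and 12369 in mock, 264 times as much, with an interval of 199 to 360. The files give no names or products for these 4 genes and no position beyond the scaffold and gene number in each identifier. The lowest log2 ratio in the authors' deposited table, -11.5, belonged to another gene with 0 estradiol reads and 1452 mock reads, which was at least 492-fold lower in estradiol when set against the limit of 3 reads.

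**Figure D1:**
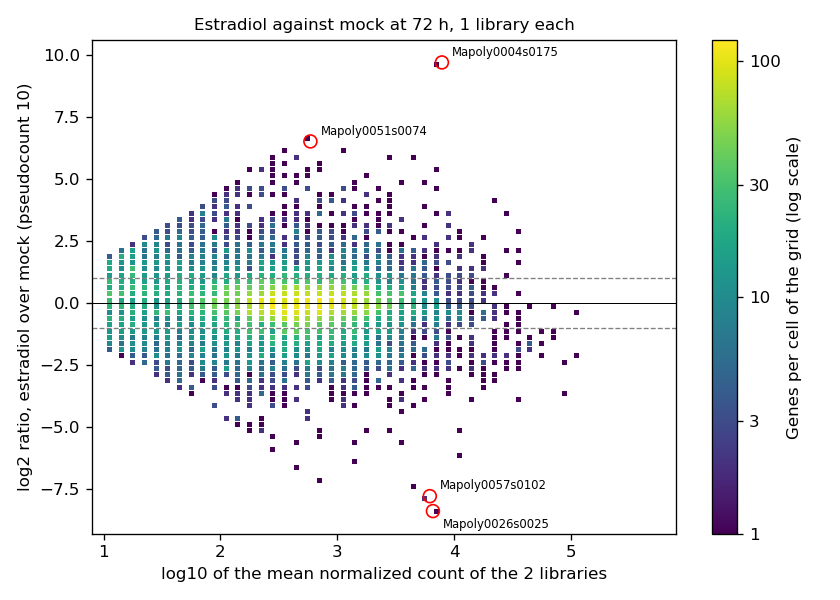
Log2 ratio of estradiol over mock (pseudocount 10) against the log10 of the mean normalized count of the 2 libraries, for the 12854 genes with a mean of 10 or more. Each square is a cell of a grid coloured by its number of genes on a log scale, dashed lines mark 2-fold, and the 4 circles mark the named genes, which lie at log2 ratios of 9.69, 6.51, -8.37 and -7.77.

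The mock library was more concentrated on a few genes than the estradiol library. Its 10 most abundant genes took 7.04% of the counts and its 100 most abundant 26.8%, against 4.28% and 18.7% in estradiol. The genes at least 2-fold higher, chosen for that direction, held 5.22% of the normalized counts in mock and 22.9% in estradiol, and the genes at least 2-fold lower held 39.1% in mock and 12.3% in estradiol. Among the 189 genes with a mean of 10000 or more, 66 (34.9%) were at least 2-fold lower in estradiol and 31 (16.4%) higher, with a median log2 ratio of -0.48 (95% order-statistic interval over genes -0.65 to -0.42). Among the 2248 genes with a mean from 1000 to 3000, 393 (17.5%) were lower and 278 (12.4%) higher, with a median of -0.03 (-0.07 to 0.00467). At the low end the balance was the other way. Of 1889 genes with a mean from 10 to 50, 506 (26.8%) were higher and 356 (18.8%) lower, with a median of 0.25 (0.18 to 0.33). Under equal totals, a setting chosen for these classes after the data had been seen, the class at 10000 or more had a median of -0.21 (-0.33 to -0.11) with 60 of 191 genes lower and 38 higher. Every class from 50 to 10000 then turned to more higher than lower genes, such as 390 higher and 293 lower from 1000 to 3000 (median 0.25), so that the excess of lower genes was left at 10000 or more alone. The turn follows from a shift of about 0.27 log2 units applied to all genes. The class at 10000 or more had a lower median than the class from 1000 to 3000 under both scalings, an order that such a shift could hardly change. The class from 10 to 50 had a median of 0.44, with 289 lower and 597 higher. An upward shift can only favour higher genes, so equal totals is no check of that class. Genes are not independent replicates, and these intervals do not describe variation between plants.

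**Figure D2:**
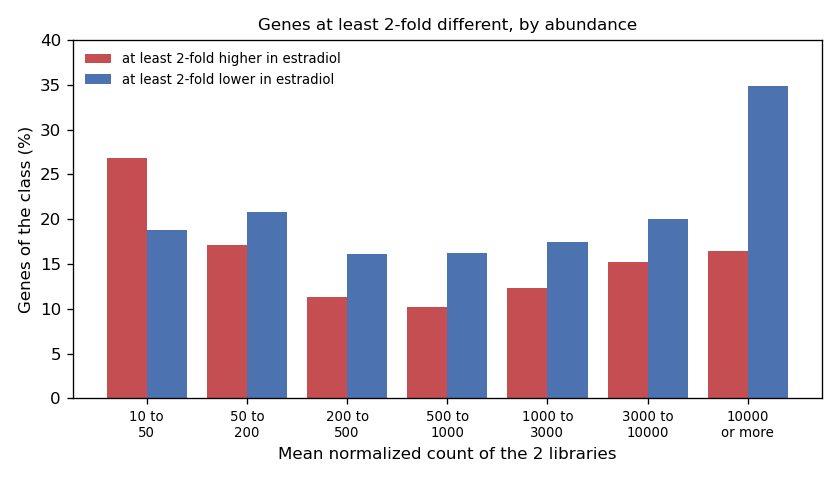
Percent of genes at least 2-fold higher (red) or at least 2-fold lower (blue) in estradiol than in mock, by classes of the mean normalized count of the 2 libraries, 1 library per group. Higher genes were more frequent from 10 to 50 (26.8% against 18.8%) and lower genes at 10000 or more (34.9% against 16.4%). Under equal totals, which raises all ratios, lower genes stayed more frequent at 10000 or more. Every class from 50 to 10000 then turned to more higher than lower genes, and the excess of higher genes from 10 to 50 could only grow.

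More genes were seen in estradiol alone than in mock alone. No mock read was found for 1240 genes and no estradiol read for 577, although the mock library was 1.18 times deeper. With at least 10 reads required in the other library, 159 genes were seen in estradiol alone and 82 in mock alone. With at least 100 reads these numbers were 14 and 8.

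The authors' deposited table made a similar division. It tagged 1677 genes as up and 2177 as down, and 12426 genes carried no tag. In the authors' deposited table, the median log2 ratio was 1.91 for genes tagged up and -1.85 for genes tagged down. Of the genes the authors' deposited table tagged up, 1625 were also at least 2-fold higher in the ratio computed here, and of those it tagged down, 2126 were at least 2-fold lower. A further 305 genes were 2-fold higher here and 211 were 2-fold lower without a tag, with a median mean normalized count of 17.5. The smallest mean of a gene tagged in the authors' deposited table was 16.4. Both sets of ratios come from the same 2 libraries and are not independent. Across genes, Spearman's rho between them was 0.997, and 0 tagged genes differed in sign.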

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

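Each group had a single library, which leaves the variation between plants unmeasured. No paired analysis was possible because each group had 1 library, and leaving out a replicate or a count model with replicates could not be run for the same reason. The alternatives for the gene lists, for the transgenes and for an adjusted p were not run, since the files held neither names nor adjusted p-values. The total of 4267 genes at least 2-fold different stayed within 1.5 times under both other pseudocounts, both other filters, both rescalings and the counting interval (2983 to 4691). The genes higher in estradiol dropped from 1930 to 1257 with a pseudocount of 50 and to 1210 with a mean of 100 or more, both of which act against genes with low counts, where higher genes were more frequent. A 1.5-fold threshold gave 6608 genes, 3129 of them higher, and a 4-fold threshold gave 1488, 667 higher and 821 lower. Lower genes outnumbered higher genes under each of these settings except equal totals (1827 lower, 2527 higher). The balance also turned at an 8-fold threshold, which was not among these settings (184 lower, 233 higher). Thresholds on the authors' probability, chosen after seeing the data, left 912 genes up and 1296 down at 0.95 or more, and 292 up and 338 down at 0.99 or more. Spearman's rho with the authors' ratio, which reflects only the pseudocount and the filter, ranged from 0.9495 to 0.99996. The log2 ratios of the 4 named genes ranged in size from 4.53 to 10.6 under the alternatives. The filters leave these ratios as they are, and the rescalings move them too little to change a sign.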

Other observations

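The patterns in this part were noticed in the data, and the tests of split gene models, of sequencing depth and of unequal totals, the scaffold counts and the values of MapolyY genes were chosen after the results had been seen. The identifiers hold a scaffold number and a gene number, and the gene numbers were taken to follow the order of genes along a scaffold, which was not tested. Among 196 scaffolds with at least 10 genes past the filter, 3 stood out in 392 two-sided Fisher's exact tests with Benjamini-Hochberg adjustment. On scaffold Mapoly0193, 14 of 18 genes were at least 2-fold lower in estradiol (18.2% of all genes; exact test, adjusted p = 2.39e-05), with a median log2 ratio of -2.63, which was -2.01 with a pseudocount of 50 and -1.79 without the filter. On scaffold Mapoly0199, 10 of 14 genes were lower (exact test, adjusted p = 0.00372), with a median of -1.51 that was -1.11 without the filter. This scaffold carried very abundant genes, which held 2.28% of the normalized counts in mock and 0.920% in estradiol. On scaffold Mapoly0180, 9 of 17 genes were higher (exact test, adjusted p = 0.0384), with a median log2 ratio of 1.16. That median was 0.50 with a pseudocount of 50, 0.55 without the filter and 0.52 with a mean of 100 or more. It was 1.69 with a pseudocount of 1, 1.33 under equal totals and 1.20 when rescaled to a median log2 ratio of 0. Genes are not replicates and neighbours are not independent, so these p-values are too small.

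Identifiers that start with MapolyY, which name sequences of the male sex chromosome, were read in both libraries. Of 48 such genes, 25 passed the filter, of which 2 were at least 2-fold higher and 0 at least 2-fold lower. Their median log2 ratio of 0.10 lay at percentile 75.2 of 10000 random lists matched on mean expression, and was 0.35 under equal totals, where the median of all genes was 0.23.

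Genes with consecutive numbers differed in the same direction more often than shuffled genes. Of 9150 such pairs, 873 were both 2-fold higher or both 2-fold lower, against a mean of 507 and a highest value of 569 in 1000 shuffles (one-sided permutation p = 0.001, the smallest that 1000 shuffles can give), and 28 runs of 3 or more consecutive genes differed 4-fold in one direction, against at most 7 in 100 shuffles. Similar abundance of neighbours does not account for it, since shuffles within 20 abundance bins gave a mean of 504. At distance 2, where a gene model split in 2 would add nothing, 630 pairs shared a direction against at most 548 in shuffles. The larger excess of consecutive genes stays open to split gene models and reads crossing a border. The excess at distance 2 stays open to gene models split in 3 or more. The excess was not seen at distance 5 (465 pairs, shuffled mean 459). Reads divided between identical neighbouring copies stay open too. The intervals of the ratio were apart for 40.7% of the 873 pairs, under the bound of 50% set in advance. Equal ratios do not hold for these 355 pairs within counting error, the only error that the intervals cover. How many shuffled pairs have intervals apart was not counted, so these pairs do not settle whether the excess over shuffling comes from copies. As a hypothesis, neighbouring genes, such as related tandem copies, may share their response to induction. Sequences of the genes would be needed to find such copies, and replicate libraries to test a shared response.

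The larger number of genes without a read in mock goes against the depth of the libraries, since the estradiol library had 0.846 times the reads of mock. The 100 most abundant genes were then removed and both libraries thinned to equal reads. The ratio of mock to estradiol genes without a read was 2.23 ± 0.02 (SD over 20 thinnings). The reads taken by these 100 genes in mock thus do not account for the larger number either. Abundant genes beyond these 100 were not removed, and the 1000 most abundant held 59.4% of the counts in mock and 54.2% in estradiol. With 1 library per group, an effect of induction and a difference between these samples unrelated to the treatment cannot be told apart.

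The lower level of the most abundant genes in estradiol depended in part on the scaling. The median log2 ratio of genes with a mean of 10000 or more was -0.48 as deposited and -0.21 (95% order-statistic interval -0.33 to -0.11) under equal totals, where 60 of 191 genes were at least 2-fold lower and 38 higher. One factor per library moves all genes alike, so these values do not decide how far the level below 0 comes from the scaling. The position relative to less abundant genes did not hang on it. Genes with a mean from 1000 to 3000 had a median of -0.03 as deposited and of 0.25 under equal totals, above the most abundant genes in both. A response to induction, a response to estradiol itself and a difference between the plants sampled all stay open, as untested.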
